A study of Homo sapiens with 20 samples.

How the data were processed

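RNA levels were measured in LNCaP cells, an androgen-responsive human prostate cancer line, with Affymetrix human genome U133 arrays, which read each transcript through sets of short probes. The labels name 5 lines, each carrying a lentiviral short hairpin RNA (shRNA) against firefly luciferase (the control, absent from human cells), HDAC1, HDAC2, HDAC3 or HDAC8. These 4 genes encode histone deacetylases, enzymes that remove acetyl groups from histones and other proteins. Each line was kept without androgen or given 1 nM R1881, a synthetic androgen, for 16 h, with the protein synthesis inhibitor cycloheximide in every culture. This gave 10 groups of 2 arrays, 20 arrays in all, and every array entered the analysis.

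The deposited values are linear intensities, 1 per probe set and array. The authors' values were scaled so that the mean of each array, after trimming 2% at each end, lay between 499.888 and 499.91, a property tested on the values themselves. The probe-level summary method is not given in the sources used here. The log2 medians of the arrays still spanned 0.39, above the limit of 0.2 set in advance, so the intensities were quantile normalized between arrays, floored at 16 and converted to log2. The plan had placed the floor before the normalization, and that order was run as an added alternative. Of the 22277 probe sets, 62 were controls, 19064 named exactly 1 gene in the platform annotation, 1043 named several and 2108 had no row in it. Of the 19064, 19052 carried a current symbol. Each of the 11963 genes was represented by its probe set with the highest mean over all arrays, and no gene was named from a probe set with several genes. The 30% of genes with the lowest mean were not tested, which left 8374. No probe set named HDAC8, so it was not measured here.

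Precision was limited by the 2 arrays per group. Between 14.5% and 21.6% of the probe sets of an array lay under the floor. A gene at the floor on every array of a group has only a bound there, so its fold change is given as "at least". The replicates of a group correlated at r of 0.968 to 0.993 across genes. Nothing states whether replicates came from separate cultures, so all p-values measure only the spread between these samples, which may be technical. The array run records gave 1 scan date and 2 scan sessions. Session 1 held the Luciferase and HDAC1 arrays and replicate 1 of both HDAC2 groups, and session 2 held the rest. Scan date could therefore not serve as a block, and scan session was added as a block instead. The control probe sets for GAPDH and ACTB at the 3' and 5' ends of the transcript gave a 3'/5' ratio for each array, a sign of RNA degradation or incomplete labelling.

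The main tests, gene lists, rule for naming genes and part of the alternatives were fixed before the data were examined. Alternatives and tests chosen later are named as such. Log2 intensities were fitted with limma 3.58.1 in R 4.3.3, with a mean for each of the 10 groups and all 20 arrays sharing the estimate of the spread (10 residual degrees of freedom, moderated with an intensity trend that added 4.59). There were 14 contrasts: R1881 in each of the 5 lines, R1881 averaged over the lines, the difference in the R1881 effect between each HDAC line and the Luciferase line, and each HDAC line against the Luciferase line without R1881. P-values were two-sided and adjusted within a contrast (Benjamini-Hochberg), and a gene passed at an adjusted p under 0.05. Each targeted transcript was also compared, 4 arrays against 4, with an exact permutation test. Androgen-induced and androgen-lowered sets for each HDAC line were defined in the 3 other HDAC lines (adjusted p under 0.05, at least 1.5-fold), so that neither line of the comparison chose its own set, and were tested with limma's fry. fry asks whether the genes of a set move one way on balance and does not compare them with other genes.

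The 23 fixed gene lists held 511 genes, of which 443 were measured. They covered androgen receptor targets (a core list and a broad list), androgen-lowered genes, sterol and lipid synthesis, polyamines, endoplasmic reticulum stress, the cell cycle, p53 targets, immediate early genes, NF-kB targets, interferon-stimulated genes, the HDAC family, corepressor complexes, histones, genes raised by HDAC inhibitors, neuroendocrine genes, luminal, basal and mesenchymal markers, ribosomal proteins, glycolysis and hypoxia, androgen receptor coregulators and lysine acetyltransferases. Basal and mesenchymal markers stand for other cell types. Each list was tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation.

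The genes named in the text were the targeted genes; the 10 largest rises and falls by R1881 in the Luciferase line and on average (same sign in all 5 lines); the 5 largest of each by R1881 in each HDAC line; the 8 largest of each for a difference between lines; and the 10 largest of each for a knockdown without R1881. Each had to pass the test, and the 2 groups compared could not overlap, except for differences between lines. Up to 4 members of each list past the threshold with the smallest adjusted p, or up to 2 by smallest p where none passed, could also be named. KLK3, KLK2, TMPRSS2 and FKBP5 were to be named in each R1881 comparison whatever their p. Genes on the Y chromosome and XIST were left out.

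Alternatives fixed in advance were median centring in place of quantile normalization, a floor of 32, no filter on dim genes, another choice of probe set, each probe set counted separately, a 1.5-fold threshold, no intensity trend, array weights, only the arrays compared, the replicate number as a block, other set tests and leaving out each replicate in turn. Alternatives chosen after seeing the data were the 3'/5' ratio as a covariate, leaving out the 5 arrays with a GAPDH 3'/5' log2 ratio over 0.7, the scan session as a block, the order of floor and normalization, a crossed replicate block, and averages and sets without the HDAC1 line. The covariate was the mean of the GAPDH and ACTB 3'/5' log2 ratios of each array. The replicate numbers did not pair the samples, as the check in the closing section shows.

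The scripts were tested on simulated data for 8374 genes, built from the mean of each gene over all arrays and its residual spread. The simulated noise was independent between genes and held no variation with the 3'/5' ratio, so the rates come from a cleaner setting than the arrays. For R1881 in the Luciferase line the test recovered 65.7% of genes changed 2-fold and 98.5% of those changed 4-fold. For the difference between the HDAC3 and Luciferase lines it recovered 37.3% and 78.8%, for the HDAC2 knockdown without R1881 62.7% and 93.9%, and for the average over the lines 97.0% and 98.5%. Of genes changed 1.5-fold it recovered 38.8%, 11.9%, 22.4% and 85.1%, in the same order. False calls made up 4.9%, 7.6%, 2.5% and 5.6% of all calls. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.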

Results

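The series asked how the loss of single histone deacetylases changes the response of LNCaP prostate cancer cells to androgen. It compared 5 knockdown lines, each without hormone and after 16 h with 1 nM R1881, a ligand of the androgen receptor. Cycloheximide, which blocks protein synthesis, was present in every culture, and its effect was not tested here. Each of the 10 groups had 2 arrays, and log2 changes are given with the standard error (SE) of the limma fit.

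The targeted transcripts were lower in the lines named for them. HDAC1 was at 23.3% of its level in the Luciferase line (log2 difference -2.10, SE 0.07, n = 4 against 4), HDAC2 at 18.1% (-2.46, SE 0.13) and HDAC3 at 29.6% (-1.76, SE 0.14). Each exact permutation test gave p = 0.0286, the smallest that the 70 splits of 4 against 4 allow, and limma's adjusted p was 1.11e-11, 1.46e-08 and 2.52e-07. HDAC2 and HDAC3 were about as low with R1881 as without it (17.6% and 18.7% for HDAC2, 30.7% and 28.5% for HDAC3). HDAC1 stood at 41.3% without R1881 and at 13.2% with it. The SE of its mean difference reflects the spread within groups and leaves this gap out. These 2 HDAC1 groups also differed in RNA quality (mean GAPDH 3'/5' log2 ratio 1.95 without and -0.03 with R1881). The gap can therefore not be assigned to R1881. HDAC8 was not measured by a probe set naming it, so the HDAC8 line was not checked in this way.

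**Figure D1:**
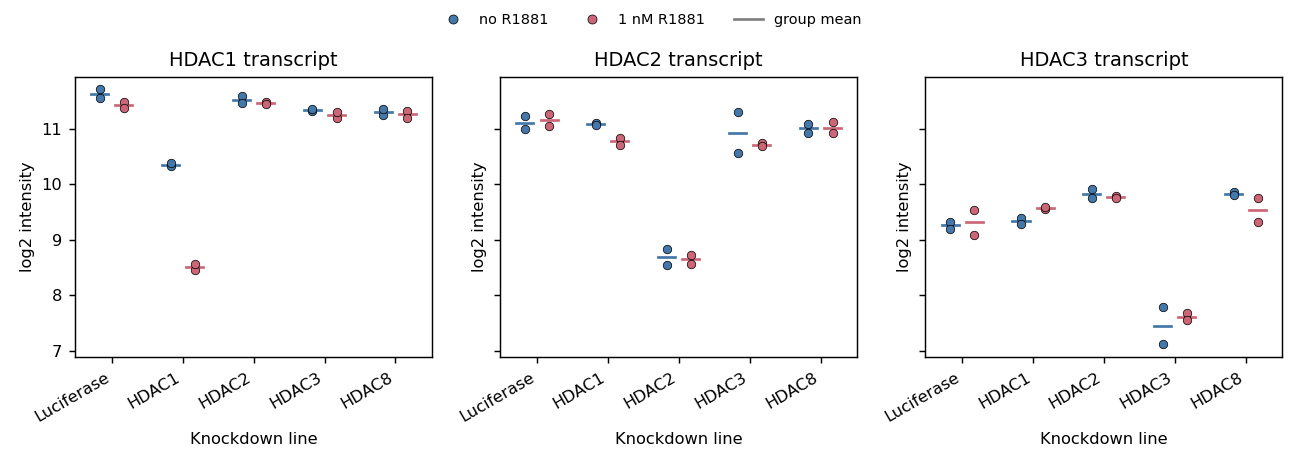
Log2 intensity of the HDAC1, HDAC2 and HDAC3 transcripts (y axis) in each of the 5 knockdown lines (x axis), as 1 point per array with the group mean as a line, blue without and red with 1 nM R1881. The targeted transcript is lowest in its own line in every panel, and in the HDAC1 line it averages 10.36 without and 8.51 with R1881.

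RNA quality differed between groups. The GAPDH 3'/5' log2 ratio, which is high where transcripts are degraded or incompletely copied, was 1.85 and 2.05 on the untreated HDAC1 arrays and -0.03 on both R1881-treated HDAC1 arrays. It was also raised on 1 untreated Luciferase array (1.22, the other 0.17), 1 R1881-treated Luciferase array (0.76, the other -0.03) and 1 untreated HDAC3 array (1.06, the other 0.11), while it reached at most 0.45 on the remaining arrays. The principal component that held the largest share of the variance (34.3%) followed this ratio over the 20 arrays (Pearson r = 0.918, permutation p = 1e-05, the smallest that 100000 resamples give; Spearman correlation 0.669, p = 0.0017). Without the 2 arrays farthest from the median ratio r was 0.724, and within the scan sessions it was 0.908 and 0.941 over 10 arrays each. It was 1 of 3 relations computed across arrays.

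**Figure D2:**
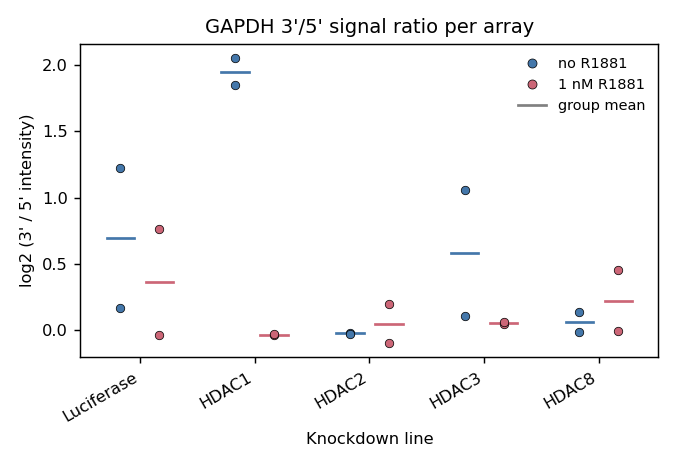
Log2 ratio of GAPDH 3' to 5' control intensity (y axis) on each array by knockdown line (x axis), with group means as lines, blue without and red with 1 nM R1881. The untreated HDAC1 arrays stand highest, at 1.85 and 2.05.

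In the Luciferase line R1881 raised well-known androgen receptor targets. PMEPA1, a membrane protein that dampens TGF-beta signalling, rose 12.7-fold (log2 3.67, SE 0.33, n = 2 against 2), the kinase SGK1 8.05-fold (3.01, SE 0.18), the membrane protease TMPRSS2 7.11-fold (2.83, SE 0.68) and the kallikrein KLK2 6.56-fold (2.71, SE 0.30). The transcription factor MAF (2.35), the Wnt pathway scaffold AXIN1 (2.26), the hormone-induced GREB1 (2.20), FAM110B (2.14), the kinase MAK (2.14) and the insulin receptor adaptor IRS2 (2.12) also rose, MAF by 1.47 with its other probe set. KLK3, which encodes prostate-specific antigen, rose 2.68-fold (1.42, SE 0.27, limma adjusted p = 0.00686). FKBP5, a cochaperone of steroid receptors, was at the floor without R1881 and at 8.62 with it, a rise of at least 24.7-fold that was outside the test because of its low mean.

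The largest falls in the Luciferase line were those of IL15RA (-2.41, SE 0.26), a subunit of the interleukin 15 receptor, the AP-1 subunit FOS (-1.91), the intestinal disaccharidase SI (-1.89), F3, which encodes tissue factor (at least 3.52-fold), AMIGO2 (-1.75), GAS2 (-1.61), the growth factor BMP2 (at least 2.83-fold), LRRC31 (-1.49), cyclin E2 (CCNE2, -1.47) and ST6GALNAC5 (-1.47). F3 and BMP2 lost their calls with a floor of 32, and IL15RA then fell by 1.43, less than each of the other 7 genes. In all, 215 of 8374 genes passed limma's test, 137 higher and 78 lower. TMPRSS2 varied widely between replicates and lost its call under several alternatives, and KLK3 lost its call with array weights (limma adjusted p = 0.0581). The count was 134 without replicate 2 of the R1881-treated Luciferase arrays, 109 with array weights, 450 with the 3'/5' ratio as a covariate (214 of the 215 among them, with the same sign) and 5 when only these 4 arrays were fitted.

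The androgen lists moved as groups in the Luciferase line. Of 17 tested core targets, 11 rose and none fell, with a median log2 change of 1.2 (limma camera adjusted p = 2.62e-26). Adjusted over the list alone, 15 rose and 1 fell. They included UAP1, an enzyme of hexosamine synthesis (1.2), and C1orf116 (1.34). Of the 83 tested genes of the broad list, 27 rose and none fell (median 0.30, adjusted p = 1.84e-24), or 34 adjusted over the list alone, among them the synaptic scaffold HOMER2 (2.10). Of 16 androgen-lowered genes, 4 fell and 1 rose (8 and 1 adjusted over the list alone; median -0.35, camera adjusted p = 4.43e-05). CCN3, a matricellular protein (-1.28), and the kinase inhibitor CAMK2N1 (-0.59) fell, while LRIG1 rose (0.83). Single members of other lists also passed, without a call for the list: the polyamine enzyme ODC1 rose (0.53), and the pioneer factor GATA2 (-1.13), the glucocorticoid receptor NR3C1 (-0.86), the immediate early factor NR4A2 (-1.06) and the vasodilator peptide gene ADM (-0.91) fell. With array weights GATA2, NR3C1, NR4A2 and LRIG1 lost their calls, NR3C1, NR4A2 and LRIG1 also lost them without the 5 arrays of high 3'/5' ratio, and ODC1 lost its call without the intensity trend.

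**Figure D3:**
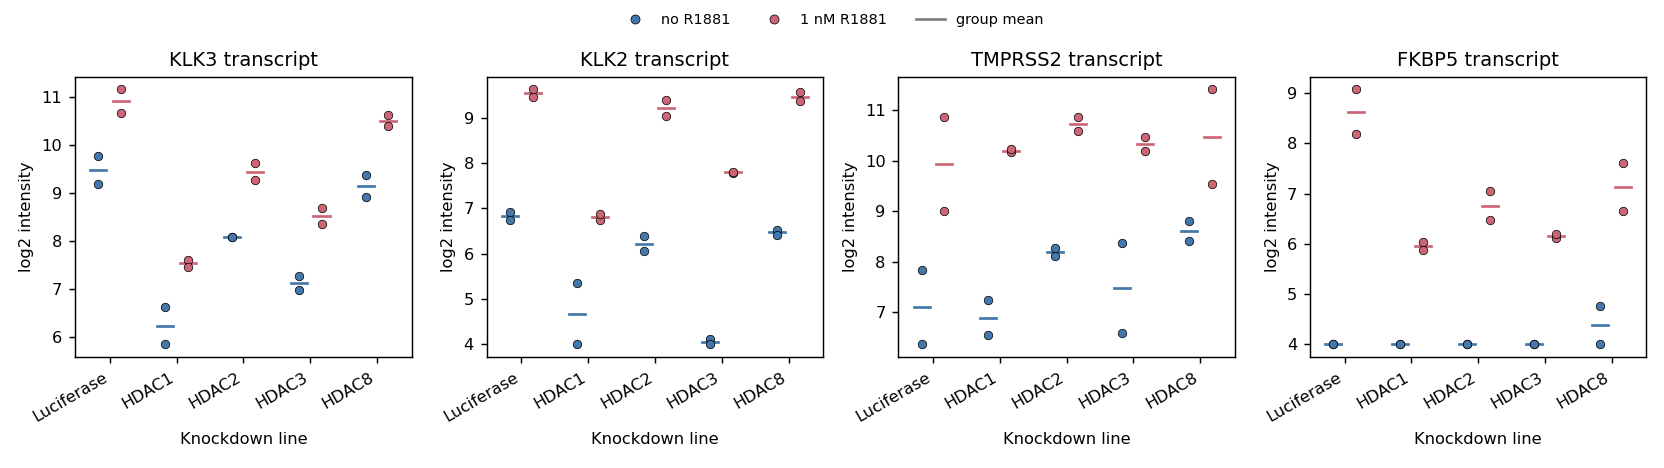
Log2 intensity of KLK3, KLK2, TMPRSS2 and FKBP5 (y axis, a separate scale in each panel) in the 5 knockdown lines (x axis), as 1 point per array with group means as lines, blue without and red with 1 nM R1881. The group means are higher with R1881 in each line, and a value of 4 is the floor.

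R1881 raised many of the same kinds of genes in the HDAC2 line. PMEPA1 (log2 3.08, SE 0.33), KLK2 (2.99, SE 0.30), the zinc finger repressor SNAI2 (2.60), MAF (2.51) and F5, which encodes coagulation factor V (2.37), showed the largest rises, and KLK3 rose 2.57-fold (1.36, SE 0.27, limma adjusted p = 0.0182). SI (-1.23), BMP2 (-1.12), the mannosidase MAN1A1 (-1.10), LRRC31 (-0.98) and ST6GALNAC5 (-0.89) showed the largest falls. TMPRSS2 was 2.54 higher without passing (limma adjusted p = 0.12), though it passed with array weights (0.00721), without the 5 arrays of high 3'/5' ratio (0.00816), with the 3'/5' covariate and with its other probe set, and FKBP5 was at least 6.75-fold higher. Of 17 core targets 10 rose, among them SGK1 (1.75) and UAP1 (1.12), and none fell (13 adjusted over the list alone; median 1.00, camera adjusted p = 2.37e-29). The broad list had 19 rises and no fall among 83 (26 adjusted over the list alone; median 0.19, adjusted p = 1.34e-22). Of 16 androgen-lowered genes 2 fell, SI and CAMK2N1 (-0.55), or 3 adjusted over the list alone (median -0.12, adjusted p = 0.00585, and 0.144 with an estimated correlation). In all 99 genes passed limma's test, 84 higher and 15 lower. The count ranged with single arrays: 63 and 46 without replicate 1 and 2 of the untreated group, and 58 and 32 without replicate 1 and 2 of the treated group. It was 233 with the 3'/5' covariate, 159 with array weights and 60 with these 4 arrays alone. KLK3 and SI lost their calls with no dim filter, and CAMK2N1 without the intensity trend.

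The HDAC8 line gave a similar profile. KLK2 (log2 2.99, SE 0.30), PMEPA1 (2.85, SE 0.33), SNAI2 (2.70), MAF (2.66) and SGK1 (2.60) showed the largest rises, KLK3 rose 2.57-fold (1.36, SE 0.27, limma adjusted p = 0.0122), and TMPRSS2 was 1.86 higher without passing (limma adjusted p = 0.305), though it passed without the 5 arrays of high 3'/5' ratio (0.0357), with the 3'/5' covariate and with its other probe set. FKBP5 was 2.75 higher. BMP2 (-1.64), ARHGAP28 (-1.41), MAN1A1 (-1.32), ST6GALNAC5 (-1.21) and SI (-1.13) showed the largest falls, with ARHGAP28 losing its call at another probe set and SI with no dim filter. Of 17 core targets 12 rose, among them the efflux transporter ABCC4 (1.5) and UAP1 (1.24), and none fell (13 adjusted over the list alone; median 1.27, camera adjusted p = 1.07e-27). The broad list showed 24 rises and no fall (31 adjusted over the list alone; median 0.25, adjusted p = 4.24e-23), including HOMER2 (1.51). Of the androgen-lowered list 3 fell and 1 rose (4 and 1 adjusted over the list alone; median -0.23, adjusted p = 0.00162, and 0.0532 with an estimated correlation), with CAMK2N1 at -0.77, the PI3-kinase subunit PIK3R3 at -0.84 and LRIG1 at 1.07.

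Other lists shifted in the HDAC8 line with no single member past the test over all genes. Sterol and lipid synthesis had a median of 0.10 (adjusted p = 0.0116, and 0.0532 with an estimated correlation; 0 of 20 adjusted over the list alone), immediate early genes -0.18 (0.0113, and 0.0532 with an estimated correlation; 1 lower of 17 adjusted over the list alone) and NF-kB targets -0.42 (0.0113, and 0.0752 with an estimated correlation; 2 lower of 8 adjusted over the list alone). In all 170 genes passed limma's test, 126 higher and 44 lower. The count was 64 and 77 without replicate 1 and 2 of the untreated group, 81 and 101 without replicate 1 and 2 of the treated group, 379 with the 3'/5' covariate and 74 with these 4 arrays alone.

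In the HDAC3 line KLK2 showed the largest rise (log2 3.73, SE 0.30), a size set by the floor, since its untreated arrays read 4.13 and 4. With a floor of 32 the rise was 2.79. The prostaglandin dehydrogenase HPGD (2.34), PMEPA1 (2.14, SE 0.33), GREB1 (2.05) and F5 (1.93) followed, and KLK3 rose 2.63-fold (1.40, SE 0.27, limma adjusted p = 0.0176). TMPRSS2 was 2.84 higher without passing (limma adjusted p = 0.0663), and 1.95 higher without the 5 arrays of high 3'/5' ratio. It passed with the 3'/5' covariate (limma adjusted p = 0.00141) and with its other probe set. FKBP5 was at least 4.46-fold higher. NPTXR (-1.61), LRRC31 (-1.60), IQSEC2 (-1.52), the transcription factor MECOM (-1.30) and ST6GALNAC5 (-1.28) showed the largest falls, and NPTXR lost its call at another probe set and without the 5 arrays of high 3'/5' ratio. MECOM and F5 lost theirs without those arrays and with array weights, and KLK3 and F5 with no dim filter. Of 17 core targets 6 rose and none fell, among them SGK1 (1.87) and UAP1 (0.78), or 13 adjusted over the list alone (median 0.78, camera adjusted p = 3.44e-15). The broad list had 13 rises and no fall (26 adjusted over the list alone; median 0.33, adjusted p = 1.29e-13), including MAF (1.67) and the ubiquitin-conjugating enzyme UBE2J1 (0.92, losing its call at another probe set). The androgen-lowered list had 1 fall, PIK3R3 (-0.73, losing its call with array weights and without those 5 arrays), and no call (1 adjusted over the list alone; adjusted p = 0.645). NF-kB targets had a median of -0.57 with no member past the test over all genes and 2 lower adjusted over the list alone (adjusted p = 0.00655, and 0.0948 with an estimated correlation).

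In all 77 genes passed limma's test in the HDAC3 line, 56 higher and 21 lower, and 1046 had an unadjusted p under 0.05. The untreated replicates differed in RNA quality, and the count was 294 without replicate 2 of them, the array with the lower 3'/5' ratio, and 39 without replicate 1. It was 43 and 36 without replicate 1 and 2 of the treated group, 181 with the 3'/5' covariate and 3 with these 4 arrays alone.

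In the HDAC1 line 4259 genes passed limma's test, 2112 higher and 2147 lower. The largest rises were those of POLD4, a subunit of DNA polymerase delta (log2 3.65, SE 0.50), the carbohydrate kinase FGGY (3.39), TMPRSS2 (3.30, SE 0.68), TRABD (3.30) and RITA1, a regulator of Notch signalling (3.14). The largest falls were those of the kinase TAOK1 (-4.23, SE 1.02), ANKRD36B (-4.04) and the zinc finger genes ZNF721 (-3.58) and ZNF160 (-3.18). The 2 groups compared here also differed most in RNA quality, with a GAPDH 3'/5' log2 ratio of 1.95 without and -0.03 with R1881. With the mean of the GAPDH and ACTB ratios as a covariate 124 genes passed, 55 of them among the 4259 with the same sign and 17 with the opposite sign. Then POLD4 (1.33), FGGY (2.34), TRABD (1.53), RITA1 (1.71), ANKRD36B (-0.69) and ZNF160 (-0.16) no longer passed, while TAOK1 (1.56), ZNF721 (0.16) and TMPRSS2 (-0.67) changed sign.

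Androgen receptor targets rose in the HDAC1 line as well, though the lists did not stand out from the other genes. KLK2 rose by 2.14 (SE 0.30), with 1 of its 2 untreated arrays at the floor, KLK3 2.46-fold (1.30, SE 0.27, limma adjusted p = 0.00173), SGK1 2.56-fold (1.35) and HOMER2 2.04-fold (1.03), KLK3 by 2.52 with the 3'/5' covariate, and FKBP5 was at least 3.90-fold higher. Of 17 core targets 7 rose and 2 fell, both over all genes and adjusted over the list alone (median 0.39, camera adjusted p = 0.199). Of the 2 that fell, the kinase gene CAMKK2 was at -0.83, and at 0.15 with its other probe set. In the broad list there were 35 rises and 13 falls (35 and 14 adjusted over the list alone; adjusted p = 0.145), with the membrane protein TMEM50A at -1.36, and no other list passed in this line. The cell cycle inhibitor CDKN1A (1.07) and the stress-induced GDF15 (1.02), both p53 targets, rose, as did 4 other members of that list, while 2 fell (6 and 2 adjusted over the list alone; adjusted p = 0.249). The 3'/5' covariate ended the calls of KLK2 (1.88), SGK1 (1.33), HOMER2 (0.99), CAMKK2 (-0.62), TMEM50A (-0.66), CDKN1A (0.55) and GDF15 (0.34). With median centring the split was 2802 higher and 1409 lower, the median of all genes moving from -0.06 to 0.12. The count was 2826 without replicate 2 of the untreated group and 2729 without replicate 2 of the treated group, and counted by probe sets it was 6550.

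Averaged over the 5 lines, 2015 genes passed limma's test for R1881, 933 higher and 1082 lower, and 251 of them by at least 1.5-fold. This average includes the HDAC1 line, whose groups with and without R1881 differed in RNA quality. The largest rises with the same sign in all 5 lines were those of KLK2 (log2 2.91, SE 0.14), TMPRSS2 (2.68), PMEPA1 (2.43), SGK1 (2.12), MAF (2.03), IRS2 (1.90), F5 (1.90), GREB1 (1.80), SNAI2 (1.78) and the alcohol dehydrogenase ADH1C (1.54). KLK3 rose by 1.37 (SE 0.12) and FKBP5 was 2.85 higher, a lower bound in 4 of the lines. The largest falls were those of ANKRD36B (-1.54), LRRC31 (-1.24), PITX1-AS1 (-1.12), LIME1 (-1.12), ST6GALNAC5 (-1.05), AMIGO2 (-1.04), the growth cone protein gene BASP1 (-1.0), the leukotriene receptor gene LTB4R (-0.99), LINC00342 (-0.93) and MAN1A1 (-0.90). LTB4R and LINC00342 lost their calls with the 3'/5' covariate, and ANKRD36B, whose average was carried by the HDAC1 line (-4.04), was then at -0.67, TMPRSS2 at 1.65 and LRRC31 at -1.2.

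Of 17 core targets 13 rose on average and none fell (14 adjusted over the list alone; median 0.94, camera adjusted p = 3.2e-16), with UAP1 at 0.94. Among the 83 genes of the broad list were 43 rises and 3 falls (49 and 6 adjusted over the list alone; adjusted p = 9.75e-16), with HOMER2 at 1.28. Of 16 androgen-lowered genes 7 fell and 1 rose, over all genes and adjusted over the list alone (median -0.16, adjusted p = 0.03, and 0.244 with an estimated correlation): SI (-0.86), the opioid receptor OPRK1 (-0.71) and PIK3R3 (-0.55) fell and LRIG1 (0.56) rose. NF-kB targets had 4 falls among 8, over all genes and adjusted over the list alone (median -0.32, adjusted p = 0.0126, and 0.127 with an estimated correlation), including the NF-kB subunit RELB (-0.62) and the interferon regulator IRF1 (-0.35). GATA2 (-0.51) and NR3C1 (-0.61) fell with no call for the coregulator list, and GATA2 and IRF1 lost their calls with the 3'/5' covariate. With median centring the split was 1172 higher and 701 lower. The 3'/5' covariate kept 578 of the 2015 genes passing on average, with the same sign. The count was 693 without the HDAC1 line and 917 with that covariate. Single arrays moved it to 1335 (without replicate 2 of the treated Luciferase group), 3072 (without replicate 2 of the untreated HDAC3 group) and 1318 (without replicate 2 of the treated HDAC8 group).

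The question the design raises most directly is whether the R1881 effect in a knockdown line differs from that in the Luciferase line. For KLK3 no difference passed: the log2 differences were -0.12, -0.06, -0.03 and -0.06 (SE 0.38 each) in the HDAC1, HDAC2, HDAC3 and HDAC8 lines. KLK2 differed by -0.58, 0.27, 1.02 and 0.27 (SE 0.43), and TMPRSS2 by 0.47, -0.29, 0.01 and -0.97 (SE 0.96), with limma adjusted p of 0.340 or above for each. The spread therefore leaves room for differences of this size, and with a floor of 32 the KLK2 difference in the HDAC3 line was 0.0813. In the HDAC1 line TMPRSS2 differed by -2.85 with the 3'/5' covariate and KLK2 by -1.08 with a floor of 32, and both then passed. FKBP5 reached 8.62 with R1881 in the Luciferase line against 5.96, 6.76, 6.16 and 7.13 in the HDAC1, HDAC2, HDAC3 and HDAC8 lines. Its difference was not tested.

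Between the HDAC1 and Luciferase lines the R1881 effect differed at 1395 genes in limma's test, 747 in the positive and 648 in the negative direction. PMEPA1 rose by 3.67 in the Luciferase line and was 0.39 higher in the HDAC1 line (difference -3.28, SE 0.47, limma adjusted p = 0.00202; -1.99 with the 3'/5' covariate). SGK1 differed by -1.65, the lipid phosphatase gene PLPP1 by -1.09, C1orf116 by -1.09 and CAMKK2 by -2.14, the latter losing its call at its other probe set. Of 17 core targets 8 differed downward and 1 upward, over all genes and adjusted over the list alone (median -0.58, camera adjusted p = 0.00108, and 0.021 with an estimated correlation). The broad list had 18 downward and 3 upward (20 and 4 adjusted over the list alone; median -0.13, adjusted p = 0.0208). The androgen-lowered genes SI (2.27), CAMK2N1 (0.99) and CCN3 (0.94) differed upward, with no call for their list (3 of 16 over all genes and adjusted over the list alone; adjusted p = 0.0781). CDKN1A (1.17) and GDF15 (1.11) also differed upward.

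The other large differences of the HDAC1 line lay at POLD4 (3.38), the DNA ligase LIG3 (3.26), TRABD (3.19), RITA1 (3.15), FGGY (3.11), the kinase STK16 (3.07), CAB39L (3.0) and the pigment cell receptor GPR143 (2.99), and at TAOK1 (-4.76), ZNF721 (-3.29), ANKRD36B (-3.01), the peptide hormone gene ADM2 (-2.95), the placental growth factor PGF (-2.88) and ZNF160 (-2.84). The HDAC1 transcript itself differed by -1.65, where the 2 HDAC1 groups also differed in RNA quality. With the 3'/5' covariate 159 genes passed, 80 of them among the 1395 with the same sign. Then POLD4, TRABD, RITA1, FGGY, GPR143, ANKRD36B, ADM2, PGF, ZNF160, ZNF721 and TAOK1 no longer passed, with TAOK1 at 0.08, and ADM2 lost its call under most other alternatives as well. The floor set part of some sizes: at 32 TAOK1 differed by -3.68 and TRABD by 2.29. CAB39L was at 2.26, STK16 at 1.91 and SI at 1.36 with the covariate. With median centring 1320 were positive and 457 negative, and with only these 8 arrays 190 passed. The count was 227 and 2665 without replicate 1 and 2 of the untreated Luciferase group, 216 and 2114 without those of the treated Luciferase group, 508 without replicate 2 of the untreated HDAC1 group, and 403 and 255 without replicate 1 and 2 of the treated HDAC1 group.

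Between the HDAC3 and Luciferase lines the R1881 effect differed at 6 genes in limma's test, 2 in the positive and 4 in the negative direction, with 320 at an unadjusted p under 0.05. The 320 are a smaller share of the 8374 genes than the 0.05 that unchanged genes would give. HOMER2 rose by 2.10 in the Luciferase line and was 0.56 higher in the HDAC3 line (difference -1.54, SE 0.19, limma adjusted p = 0.00447). SOCS2, a feedback inhibitor of cytokine signalling, rose by 1.43 and was 0.06 higher (-1.37, SE 0.17), C1orf116 1.34 and 0.37 (-0.98), and CDC42EP3 0.93 and 0.00 (-0.94). IL15RA fell by 2.41 in the Luciferase line and was 0.32 higher in the HDAC3 line (2.73, SE 0.37), and the receptor adaptor GRB10 was 0.89 and 0.14 lower (0.75). IL15RA lost its call with a floor of 32, at 1.75. C1orf116, CDC42EP3 and GRB10 lost theirs with array weights, with the session as a block, without the intensity trend and without the 5 arrays of high 3'/5' ratio, and HOMER2 lost its call with array weights (limma adjusted p = 0.122). Only SOCS2 kept its call under all of these. The core list had a median difference of -0.43 with 1 of 17 lower (5 adjusted over the list alone; camera adjusted p = 0.000645, and 0.0129 with an estimated correlation). The broad list had -0.09 with 1 of 83 lower (6 adjusted over the list alone; adjusted p = 0.00257), and the androgen-lowered list 0.27 with none of 16 past the test (3 higher adjusted over the list alone; adjusted p = 0.00282, and 0.109 with an estimated correlation). The count was 31 with the 3'/5' covariate and 3 without replicate 1 of the treated Luciferase group, replicate 2 of that group, or replicate 1 of the untreated HDAC3 group. It was 10 without replicate 2 of the untreated Luciferase group and 0 without replicate 2 of the treated HDAC3 group in limma's test (320 with all arrays at an unadjusted p under 0.05).

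No gene differed in its R1881 effect between the HDAC2 or HDAC8 line and the Luciferase line (0 in limma's test each, with 230 and 236 at an unadjusted p under 0.05). Both are smaller shares of the 8374 genes than the 0.05 that unchanged genes would give. SGK1 differed by -1.26 (limma adjusted p = 0.219) and PLPP1 by -0.40 (limma adjusted p = 1, and 0.017 with the 3'/5' covariate) in the HDAC2 line. There the core list had a median difference of -0.18 (0 of 17, and 1 lower adjusted over the list alone; camera adjusted p = 0.0115, and 0.061 with an estimated correlation) and the broad list -0.11 (0 of 83, and 2 lower adjusted over the list alone; adjusted p = 0.0115, and 0.0252 with an estimated correlation). In the HDAC8 line neither passed (adjusted p = 0.601 and 0.571), while cell cycle genes had a median difference of 0.21 with none of 31 past the test over all genes or adjusted over the list alone (adjusted p = 0.0373, and 0.681 with an estimated correlation). With the 3'/5' covariate 13 and 7 genes passed, and without replicate 1 of the untreated Luciferase group 1 gene passed for the HDAC8 line.

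Sets of androgen-responsive genes chosen in the other HDAC lines gave a further comparison. The 117 induced genes rose by a mean of 0.53 in the HDAC1 line and 1.05 in the Luciferase line (difference -0.52, limma fry adjusted p = 1.24e-05 over the 8 sets), and 80 of them rose less in the HDAC1 line. The 45 lowered genes fell by a mean of 0.50 and 0.87 (difference 0.37, limma fry adjusted p = 0.00156), with camera p = 0.0537 at an estimated correlation. The sets for the HDAC2 line (324 and 358 genes; -0.22 and 0.29), the HDAC3 line (165 and 110 genes; -0.08 and -0.15) and the HDAC8 line (321 and 320 genes; -0.18 and 0.21) showed no difference past the test (fry p between 0.321 and 0.678 in limma). These 3 lines drew on sets that the HDAC1 line, with its uneven RNA quality, helped to define. With sets defined without it, the difference for induced genes in the HDAC3 line was -0.24 and that for lowered genes 0.27, while for lowered genes in the HDAC2 line it was 0.25, each past fry's unadjusted threshold of 0.05 in limma. Without replicate 1 of the untreated Luciferase group the induced set of the HDAC3 line differed by -0.23, just past that threshold.

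Without R1881 the HDAC8 line stood out by interferon-stimulated genes. The chemokine genes CXCL11 and CXCL10 were 45.2-fold and 36.0-fold higher than in the Luciferase line (log2 5.50, SE 0.38, and 5.17, SE 0.13), and the antiviral genes RSAD2 (4.73), IFIT2 (4.37), IFIT1 (4.06), OASL (3.90), OAS1 (3.84) and IFIT3 (3.61) were among the 10 largest rises with CCL5 (3.62) and CCL20, a chemokine gene that was at least 22-fold higher. Of 22 interferon-stimulated genes 20 rose and none fell, over all genes and adjusted over the list alone (median 2.47, camera adjusted p = 1.19e-25; median 2.64 with the scan session as a block). NF-kB targets rose in 4 of 8 with no fall, also adjusted over the list alone (median 0.83, adjusted p = 0.00095), with IRF1 at 1.36, TNFAIP3 at 1.04 and RELB at 0.88. Immediate early genes had 8 rises and 1 fall among 17 (10 and 1 adjusted over the list alone; median 0.47, adjusted p = 0.00718), with EGR1 at 1.75, JUNB at 0.73 and NR4A2 at -1.06. The androgen-lowered list had 8 rises and 1 fall among 16 (9 and 2 adjusted over the list alone; median 0.68, adjusted p = 0.000283), with SI at 2.12, CAMK2N1 at 2.03, the pseudokinase TRIB1 at 1.44 and the glucuronosyltransferase UGT2B15 at 1.04.

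**Figure D4:**
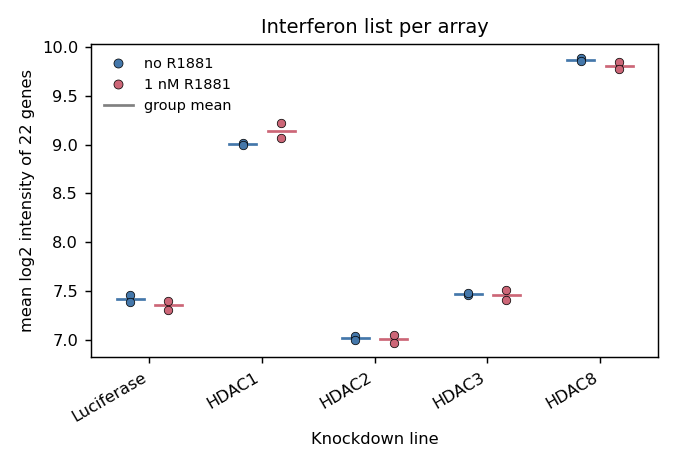
Mean log2 intensity of the 22 tested interferon-stimulated genes (y axis) on each array by knockdown line (x axis), with group means as lines, blue without and red with 1 nM R1881. The HDAC8 arrays lie between 9.78 and 9.89 and the Luciferase arrays between 7.31 and 7.46. The median over genes of the difference between these lines, which is not plotted, is 2.47 without and 2.34 with R1881.

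The largest falls in the untreated HDAC8 line were those of PRR36 (-3.64, and -2.81 with a floor of 32), ZNF324 (-2.79), the GABA-degrading enzyme ALDH5A1 (-2.58), the sulfonylurea receptor ABCC8 (-2.39), the adhesion molecule MCAM (-2.35), TSC22D3, a glucocorticoid- and androgen-induced gene (-2.25), ANP32E (-2.24), APLP1 (-2.17), OSBPL11 (-2.13) and DRC8 (-2.10). ABCC8 lost its call with the session as a block and without the 5 arrays of high 3'/5' ratio. NR4A2 and RELB also lost theirs with the session as a block, as did UAP1, and JUNB without those 5 arrays. ABCC4 (-0.97) and UAP1 (-0.48) were lower, with 5 of 17 core targets down and 1 up (6 and 1 adjusted over the list alone; camera adjusted p = 0.23). In all 1878 genes passed limma's test, 828 higher and 1050 lower, and 1251 of them by at least 1.5-fold. All HDAC8 arrays were scanned in session 2 and all Luciferase arrays in session 1, so no value within a session exists. With the session as a block, which rests on the HDAC2 arrays, 722 genes passed. The GAPDH 3'/5' log2 ratio averaged 0.06 here and 0.70 in the untreated Luciferase group. With the 3'/5' covariate 2383 genes passed, 1214 higher and 1169 lower, and 1502 of the 1878 were among them with the same sign. The excess of lower genes did not hold in that fit. The count was 1188 without replicate 2 of the untreated Luciferase group, 985 and 1024 without replicate 1 and 2 of the untreated HDAC8 group, and 626 with these 4 arrays alone.

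In the HDAC1 line interferon-stimulated genes were higher as well. OASL (log2 3.49, SE 0.14), RSAD2 (2.99), OAS1 (2.83) and IFIT3 (2.16) rose, with 18 rises and no fall among 22, over all genes and adjusted over the list alone (median 1.57, camera adjusted p = 2.05e-09, and 0.00157 with an estimated correlation). The other largest rises were those of the secreted phospholipase PLA2G2A (3.40), the RNA-binding RBPMS (3.09), LRRC31 (3.09), the antiviral ZC3HAV1 (3.08), the trefoil peptide TFF1 (3.06), CCL5 (3.03), CITED1 (3.03) and CXCL10 (2.85). The largest falls were those of the GABA transaminase ABAT (-5.35, SE 0.18), POLD4 (-4.18), the prostaglandin receptor PTGFR (-4.06), PNMA2 (-4.01), the fatty acid elongase ELOVL4 (at least 14.9-fold), MSRB1 (-3.85), ABCC8 (-3.41), BCCIP (-3.35), the cholesterol esterifying SOAT1 (-3.34) and THNSL1 (-3.33, and -2.73 with a floor of 32). The 3'/5' covariate moved POLD4 to -2.74, SOAT1 to -2.75, ABCC8 to -4.12 and CCL5 to 2.40.

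The p53 targets were lower in the untreated HDAC1 line, with no rise and 9 falls among 14 (10 adjusted over the list alone; median -0.87, camera adjusted p = 9.95e-05, and 0.00923 with an estimated correlation). BAX, a promoter of apoptosis (-2.73), the DNA damage sensor DDB2 (-2.51), ZMAT3 (-2.37) and CDKN1A (-2.23) fell, DDB2 by 1.57 with the 3'/5' covariate. KLK3 (-3.25), KLK2 (-2.15, and -1.65 with a floor of 32) and TSC22D3 (-1.76) were lower and CAMKK2 higher (1.60), with 6 core targets up and 6 down (7 and 6 adjusted over the list alone; adjusted p = 0.922), and acid phosphatase ACP3 was at -2.60. CAMKK2 lost its call at its other probe set. In all 4098 genes passed limma's test, 1987 higher and 2111 lower, or 1265 and 3015 with median centring, which set the median change of all genes at -0.21. The GAPDH 3'/5' log2 ratio averaged 1.95 here and 0.70 in the untreated Luciferase group. With the 3'/5' covariate 3189 genes passed, 2230 of them among the 4098 with the same sign, the interferon median was 1.52 and 9 p53 targets fell with 1 rise. With these 4 arrays alone 2703 passed.

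In the untreated HDAC3 line cell cycle genes were lower. The ribonucleotide reductase subunit RRM2 (log2 -2.65, SE 0.31), topoisomerase TOP2A (-2.40), CCNE2 (-2.10) and thymidylate synthase TYMS (-1.96) fell, with 19 falls and no rise among 31 genes (22 and 1 adjusted over the list alone; median -1.07, camera adjusted p = 6.44e-10, and 0.112 with an estimated correlation). DTL, a ubiquitin ligase subunit of replication (-2.60), and MYBL1 (at least 5.52-fold) were also among the largest falls, with PCTP (-2.84), KLK2 (-2.76, and -1.83 with a floor of 32), the androgen-glucuronidating UGT2B28 (-2.75), CRIPT (-2.71), MINDY2 (-2.44) and DRC8 (-2.43). With the session as a block RRM2 was at -2.05, TOP2A at -1.72, DTL at -1.97 and UGT2B28 at -1.90, and PCTP was at -2.15 without the 5 arrays of high 3'/5' ratio. KLK3 was at -2.36 and ACP3 at -1.82, and 9 of 17 core targets fell with 1 rise, over all genes and adjusted over the list alone (median -0.41, adjusted p = 0.0459, and 0.112 with an estimated correlation).

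CCL20 was at least 14.6-fold higher in the untreated HDAC3 line, and the immune locus transcript HCP5 (3.19), the matrix proteoglycan LUM (3.11), CAMK2N1 (3.08), DOK5 (2.87), the collagen COL5A2 (2.83), MATN2 (2.81), LRP3 (2.69), AXIN1 (2.60) and the transporter SLCO4A1 (2.55) followed. HCP5 lost its call with the session as a block, at 1.39, LUM was then at 3.90, and AXIN1 was at 1.87 without the 5 arrays of high 3'/5' ratio. NF-kB targets rose in 4 of 8 with no fall (5 adjusted over the list alone; median 0.80, adjusted p = 0.0015, and 0.112 with an estimated correlation), with RELB at 1.46, TNFAIP3 at 1.08 and IRF1 at 0.88. Interferon-stimulated genes had 3 rises, among them ISG20 (1.02) and RSAD2 (0.96, losing its call with array weights), and 3 falls, among them OASL (-0.83) and ISG15 (-0.78), over all genes and adjusted over the list alone (median 0.12, adjusted p = 0.98). In all 2316 genes passed limma's test, 1170 higher and 1146 lower, or 965 and 1477 with median centring. Sessions separate this line from the Luciferase line too, and with the session as a block 974 genes passed. The GAPDH 3'/5' log2 ratio averaged 0.58 here. The count was 3499 with the 3'/5' covariate, with all 2316 among them, 1055 with array weights and 218 with these 4 arrays alone.

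In the untreated HDAC2 line BMP2 (log2 2.74, SE 0.23), CAMK2N1 (2.40, SE 0.11), PRR16 (2.33), MAPK8IP1 (2.32), LUM (2.29), TSHZ2 (2.24), DHX35 (2.08), ADPRM (2.04), TRIM29 (1.99) and DAGLA (at least 3.80-fold) showed the largest rises. FOS (-3.04), the interferon-induced GTPase GBP1 (-2.82), GADD45B (-2.66), ARHGDIB (at least 5.87-fold), the corepressor TLE4 (-2.55), HDAC2 itself (-2.42), MCAM (-2.42), EBLN2 (-2.27), MAFF (-2.27) and the matricellular CCN2 (-2.21) showed the largest falls. DAGLA lost its call with a floor of 32, GADD45B at another probe set, and ADPRM under several alternatives. TRIM29 was at 1.05 with a floor of 32. Without the 5 arrays of high 3'/5' ratio DHX35 was at 0.81, EBLN2 at -1.45 and CCN2 at -2.80, and MAPK8IP1 was at 1.65 with the 3'/5' covariate. Of 16 androgen-lowered genes 8 rose and 1 fell (12 and 1 adjusted over the list alone; median 0.99, camera adjusted p = 8.63e-06, and 0.0401 with an estimated correlation), including SI (1.92), UGT2B15 (1.18) and the cholinesterase BCHE (1.07). KLK3 was lower (-1.40), with 5 core targets down and 1 up (6 and 2 adjusted over the list alone; adjusted p = 0.178).

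Interferon-stimulated genes moved the other way in the HDAC2 line, with 9 falls and no rise among 22, over all genes and adjusted over the list alone (median -0.30, adjusted p = 0.0181, and 0.106 with an estimated correlation). TRIM22 (-1.81), ISG15 (-1.33), OASL (-1.20) and IFIT3 (-0.87) fell. Of 31 cell cycle genes 11 fell and 1 rose (12 and 1 adjusted over the list alone; median -0.35, adjusted p = 0.0428, and 0.434 with an estimated correlation), among them CCNE2 (-1.33), CCNA2 (-1.0), UBE2C (-0.95) and PCNA (-0.92). Of 14 p53 targets 5 fell and none rose (6 adjusted over the list alone; median -0.42, adjusted p = 0.0387, and 0.106 with an estimated correlation), with ZMAT3 at -1.65. In all 1692 genes passed limma's test, 738 higher and 954 lower. The GAPDH 3'/5' log2 ratio averaged -0.02 here. With the 3'/5' covariate 1858 genes passed, 958 higher and 900 lower, and 1210 of the 1692 were among them with the same sign. The excess of lower genes did not hold in that fit. With the session as a block 1243 genes passed. The count was 880 without replicate 2 of the untreated Luciferase group, 1016 and 705 without replicate 1 and 2 of the untreated HDAC2 group, and 442 with these 4 arrays alone.

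Across the 4 knockdowns without R1881, 177 genes were higher and 190 lower in every line, against 2.42 and 4.13 for independent lists of the same lengths. All 4 comparisons share the same 2 Luciferase arrays, so the lists are not independent and these 2 numbers are no chance level for them. Across 8374 genes, which are not independent, the log2 changes of the HDAC2 and HDAC8 lines correlated at r = 0.664 (covariance 0.188), those of HDAC3 and HDAC8 at 0.603 (0.192), HDAC2 and HDAC3 at 0.562 (0.165), HDAC1 and HDAC3 at 0.396 (0.183), HDAC1 and HDAC8 at 0.27 (0.121) and HDAC1 and HDAC2 at 0.0551 (0.0227). In 100 simulations of unchanged lines against shared controls r was 0.497 and the covariance 0.0336. Noise of equal size in both lines and the control sets that r by construction, so it is no benchmark for lines with real changes. The simulated noise was also independent between genes and held no variation with the 3'/5' ratio. A further comparison shared no Luciferase arrays but crossed the hormone states. The change of 1 line without R1881 was set against that of the other with R1881. Each change was taken against the Luciferase group of the same hormone state. Averaged over the 2 ways round, r was 0.505 for HDAC2 and HDAC8, 0.556 for HDAC3 and HDAC8 and 0.54 for HDAC2 and HDAC3. It was 0.326 for HDAC1 and HDAC3, 0.463 for HDAC1 and HDAC8 and 0.29 for HDAC1 and HDAC2. Part of the overlap may come from the shared controls.

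For 14 of the 23 lists camera passed in none of the 14 contrasts, the smallest adjusted p being 0.0781. By list the smallest adjusted p was 0.182 for polyamine genes, 0.0781 for endoplasmic reticulum stress and for genes raised by HDAC inhibitors, 0.213 for the HDAC family, 0.351 for corepressor complexes, 0.269 for histones, 0.326 for neuroendocrine genes, 0.126 for luminal markers and for glycolysis and hypoxia, 0.232 for ribosomal proteins, 0.354 for androgen receptor coregulators and 0.308 for lysine acetyltransferases. Markers of other cell types gave 0.405 (basal, 4 genes tested) and 0.2 (mesenchymal, 5 genes tested). Single members of these lists did change without R1881: the mesenchymal filament gene VIM was higher in the HDAC2 (1.68), HDAC3 (1.09) and HDAC8 (1.93) lines, and the luminal marker STEAP1 was higher in the HDAC2 (1.22), HDAC3 (1.14) and HDAC8 (1.08) lines and lower in the HDAC1 line (-1.06).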

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

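The covariate tests of the induced sets in the HDAC1 and HDAC3 lines and the sets defined without the HDAC1 line were chosen after those results were seen. Most results here were singled out because the R1881 effect differed between an HDAC line and the Luciferase line in a test of that difference. In the HDAC1 line these were 1395 genes, among them PMEPA1 (-3.28), TAOK1 (-4.76), ZNF721 (-3.29), ANKRD36B (-3.01), ADM2 (-2.95), PGF (-2.88), ZNF160 (-2.84), POLD4 (3.38), LIG3 (3.26), TRABD (3.19), RITA1 (3.15), FGGY (3.11), STK16 (3.07), CAB39L (3.0) and GPR143 (2.99), and the HDAC1 transcript (-1.65). The core and broad androgen lists differed by medians of -0.58 and -0.13 in the HDAC1 line, -0.18 and -0.11 in the HDAC2 line and -0.43 and -0.0853 in the HDAC3 line.

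In the HDAC3 line 6 genes differed: HOMER2 (-1.54), SOCS2 (-1.37), C1orf116 (-0.98), CDC42EP3 (-0.94), GRB10 (0.75) and IL15RA (2.73). The androgen-lowered list differed there by a median of 0.27, and the cell cycle list by 0.21 in the HDAC8 line. The sets chosen in other lines differed by -0.52 (induced) and 0.37 (lowered) in the HDAC1 line. A signal outside the main measurement was the GAPDH 3'/5' log2 ratio of the untreated HDAC1 arrays, 1.85 and 2.05, above the highest value of the Luciferase arrays (1.22).

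The 4259 genes that R1881 changed in the HDAC1 line, such as POLD4 and ANKRD36B, may largely reflect RNA quality. Across genes, the R1881 change in that line correlated at r = -0.80 with the slope on the 3'/5' ratio within the groups of the other lines, which did not include the HDAC1 arrays. Computed in the same way for each other line, r was -0.54 (HDAC3), -0.23 (Luciferase), 0.20 (HDAC2) and 0.19 (HDAC8). The HDAC3 value also lay past the limit of -0.5 set in advance for the HDAC1 line. An androgen response shared with the HDAC2 and HDAC8 lines was unlikely as the main source. The correlation with their mean change was r = -0.0896, against 0.498 for the Luciferase line. Taken over all genes, this value does not exclude a shared response at androgen-responsive genes. R1881 and RNA quality cannot be separated fully within this line, because the ratio differed between its 2 groups far more than within them.

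The smaller rise of androgen-induced genes in the HDAC1 line remained in a fit with the 3'/5' ratio as a covariate. The mean difference of the set was then -0.47 over the 121 genes that made it up, past fry's unadjusted threshold of 0.05 in limma. It was -0.52 over 117 genes without the covariate. This fit cannot exclude RNA quality as the cause. Its slope rests on differences within groups, while the mean GAPDH 3'/5' log2 ratio of this line was 1.95 without and -0.03 with R1881. A floor on the signal did not account for the smaller rise. Without the genes near the floor the difference was -0.53 over 109 genes, also past fry's unadjusted threshold. A weaker androgen response after loss of HDAC1 would also give this pattern, and other properties of the line stay open, since the number of hairpins is not stated.

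For androgen-induced genes in the HDAC3 line the set of 165 genes differed by -0.08 without passing, so there was no smaller rise to explain in that fit. The covariate fit gave -0.21 over a set of 128 genes, past fry's unadjusted threshold in limma, and sets defined without the HDAC1 line gave -0.24 with no covariate. Fit and set membership changed together, so these values do not decide on RNA quality. Across genes, the R1881 change in the HDAC3 line correlated at r = -0.54 with the slope on the 3'/5' ratio within the groups of the other lines. RNA quality therefore stays open as a source of the R1881 changes in this line. Leaving out the genes near the floor gave -0.0906 over 157 genes, which could not inform on the floor, since the whole set had started from a difference of that size. HOMER2 (-1.54) lost its call with array weights.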

How the results depend on the processing

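The lower HDAC1, HDAC2 and HDAC3 transcripts and the smaller rise of induced genes in the HDAC1 line kept their direction and their call under every alternative that could be run for them. Leaving out the 5 arrays of high 3'/5' ratio removed both untreated HDAC1 arrays. That alternative therefore gave no value for the HDAC1 transcript or for the sets in the HDAC1 line. The count of genes differing between the HDAC3 and Luciferase lines was 3 without the intensity trend, with the replicate block, with the session block and by probe sets, 2 with array weights and 10 with no dim filter. For HDAC2 it was 9 with no dim filter, 2 with other probe sets chosen, and 1 with array weights, a floor of 32, by probe sets or without the 5 arrays. Array weights gave 109 genes for R1881 in the Luciferase line, 159 in the HDAC2 line and 1055 for HDAC3 without R1881. With only the arrays compared, where fewer samples estimate the spread, R1881 gave 5 (Luciferase), 60 (HDAC2), 3 (HDAC3) and 74 (HDAC8) genes, the differences 190 (HDAC1) and 0 (HDAC3, limma; 320 at an unadjusted p under 0.05 with all arrays), and the knockdowns 2703, 442, 218 and 626. At least 1.5-fold left 251 on average and 1251 for HDAC8 without R1881, and R1881 in the HDAC1 line gave 6550 probe sets. With the 3'/5' covariate R1881 gave 450, 124, 233, 181 and 379 genes in the Luciferase, HDAC1, HDAC2, HDAC3 and HDAC8 lines and 917 on average, the differences 159, 13, 31 and 7, and HDAC3 without R1881 3499. The session block gave 974 (HDAC3) and 722 (HDAC8) without R1881, and the average without the HDAC1 line 693. The cause was not tested.

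For the sets, camera with an estimated correlation gave p = 0.0537 for lowered genes in the HDAC1 line (0.37). The preset correlation gave calls for HDAC2 (-0.22 and 0.29, limma camera p = 1.91e-09 and 4.15e-08), HDAC3 (-0.0771 and -0.15, p = 0.0244 and 0.0486) and HDAC8 (-0.18 and 0.21, p = 0.00012 and 0.000353). The core list in place of the set gave -0.21 (HDAC2) and -0.25 (HDAC3). For lowered genes in the HDAC2 line and induced genes in the HDAC3 line the covariate gave 0.25 and -0.21, leaving out the 5 arrays 0.20 and -0.24, and sets defined without the HDAC1 line 0.25 and -0.24. The last also reversed lowered genes in the HDAC3 line, to 0.27. Signs also reversed with the covariate for R1881 in the HDAC1 line at TAOK1 (1.56), TMPRSS2 (-0.67) and ZNF721 (0.16), and for its difference from the Luciferase line at TAOK1 (0.0788) and TMPRSS2 (-2.85), and with other probe sets at CAMKK2 (0.15). The cause was not tested.

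Leaving out single arrays gave 134 to 213 genes for R1881 in the Luciferase line, 2729 to 3536 in HDAC1, 32 to 63 in HDAC2, 36 to 294 in HDAC3, 64 to 101 in HDAC8 and 1318 to 3072 on average. The differences gave 216 to 2665 (HDAC1), 0 to 10 (HDAC3) and 0 to 1 (HDAC8), with 0 throughout for HDAC2 in limma's test (230 with all arrays at an unadjusted p under 0.05). The knockdowns gave 2757 to 4242, 705 to 2065, 1874 to 2038 and 985 to 2027. The transcripts stayed within -2.14 to -2.06 (HDAC1), -2.53 to -2.39 (HDAC2) and -1.93 to -1.59 (HDAC3). The induced and lowered sets ranged from -0.54 to -0.51 and 0.31 to 0.44 (HDAC1), -0.50 to 0.05 and 0.02 to 0.56 (HDAC2), -0.23 to 0.0736 and -0.40 to 0.11 (HDAC3), and -0.49 to 0.13 and -0.07 to 0.50 (HDAC8). Replicate numbers did not pair: of 45 pairs of groups 10 had a correlation of replicate differences over 0.1 and 17 under -0.1 (-0.59 to 0.59). The replicate block gave 193 for R1881 in the Luciferase line, and a block with the numbers crossed where they ran opposite 190. A block for scan date could not be run, with 1 date, nor a test of the HDAC8 transcript.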

Other observations

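The tests of a response common to all hairpin lines and of a single hairpin were chosen after the interferon result was seen, and the others of this part before. CAMK2N1, an inhibitor of the calcium-dependent kinase CaMKII, was higher than in the Luciferase line by 2.65 (HDAC1), 2.40 (HDAC2), 3.08 (HDAC3) and 2.03 (HDAC8) in log2 units (SE 0.11 each, n = 2 against 2), and R1881 lowered it by 0.59 in the Luciferase line. SI, which R1881 also lowered, was higher by 1.92, 2.14 and 2.12 in the HDAC2, HDAC3 and HDAC8 lines. Other androgen-lowered genes moved the other way: DDC (-3.00) and CXCR4 (-1.75) fell in the HDAC1 line and CXCR4 (-1.44) in the HDAC3 line, where the list did not pass. The prostatic acid phosphatase gene ACP3 was lower by 2.60, 1.82 and 1.19 in the HDAC1, HDAC3 and HDAC8 lines. These comparisons share the 2 Luciferase arrays.

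The interferon-stimulated genes kept their order between lines with R1881. The list median against the Luciferase line was 1.57 without and 1.92 with R1881 in the HDAC1 line, -0.30 and -0.36 in HDAC2, 0.12 and 0.20 in HDAC3, and 2.47 and 2.34 in HDAC8, where all 22 genes were higher in both states. In the untreated HDAC1 line the NF-kB targets TNFAIP3 (1.51) and RELB (1.25) rose, while PCNA (-2.75) and TYMS (-2.25), genes of DNA synthesis, fell. These are single members: neither the NF-kB list nor the cell cycle list passed camera in that comparison.

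The higher interferon-stimulated genes of the HDAC8 line, such as CXCL10, could in principle come from RNA quality, from the scan session or from the transduction. With the 3'/5' covariate the median stayed at 2.41, and at 1.52 in the HDAC1 line. Between the HDAC2 arrays of the 2 sessions the list differed by -0.0864. The higher of the HDAC2 and HDAC3 medians was 0.12, so the rise over the Luciferase line was not common to the HDAC lines. The Luciferase line also carried a lentiviral hairpin. A response common to all hairpin lines would therefore cancel in these differences, and the medians could not have shown it. A response to the particular hairpin stays open, since the labels give 1 line per target and do not state the number of hairpins.

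For R1881 averaged over the lines, a fit of line and R1881 gave 909 genes. Among 100 ways of splitting the 20 arrays into 10 and 10 only 1, the real split, gave as many, the highest of the others being 6. The other splits were drawn without regard to group, which left the R1881 effect and the quality difference of the HDAC1 line in the residual spread. Low counts were therefore likely in them. RNA quality in the HDAC1 line differed along the real split, so these counts do not separate it from R1881.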
